A study of Homo sapiens with 6 samples.

How the data were processed

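RNA from MIA PaCa-2 cells, a human pancreatic carcinoma line, was sequenced in 6 libraries. Per the labels, 3 libraries came from cells carrying the empty vector and 3 from cells overexpressing the long noncoding RNA LINC00901. Replicates carry the numbers 1 to 3 in each group. The labels do not say whether they were separate cultures, so p-values measure only the spread between these samples, which may be technical.

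The deposited values are FPKM, fragment counts scaled to gene length and library total, with 1 value per gene and library and at most 2 decimals. Per the submitters' processing notes, cutadapt, FastQC and HISAT2 were used with the human build hg19. Their versions are not given in the sources used here, and neither is the tool that made the FPKM values. The table has 18268 rows, of which 990 join several gene names and 33 share a name with another row. A joined row is reported under all of its names, because its value cannot be assigned to a single gene. No row names LINC00901, so the level of the overexpressed RNA was not analysed here. Of the rows, 3750 are listed at 0 in all 6 libraries. They include all 13 rows of mitochondrially encoded genes, which every cell uses, so a 0 in this table can be a failed estimate and is reported only as listed at 0.

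The depth of each library is unknown. Low values were checked for whole-read steps. Among 105 low genes in the vector libraries, 21.9% of value ratios lay within 0.1 log2 of a power of 2, and among 13 low genes in the overexpression libraries 23.1% did. No whole reads were recovered from these, so no count model and no counting interval was used. The labels give no batch or date.

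Values were transformed to log2(FPKM + 0.5). Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 9694 rows. The groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend and no replicate block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A fold change on this scale understates the change of low genes. Because the median gene differed between the groups, log2 changes of named genes are given relative to the median gene of the 9694, while the adjusted p-values are those of the unscaled fit.

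In advance, 38 gene lists were fixed, and 32 of them had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. Camera compares a list with all other genes. Fry asks whether the members move, on balance, in a single direction, and makes no comparison with other genes. Named genes followed a rule fixed at the same time. It takes MYC, IGF2BP1, IGF2BP2 and IGF2BP3, then the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 1 FPKM in the higher group and groups that do not overlap. It adds up to 4 members of each list that passed camera or had at least 3 members past the threshold, in order of absolute change. An item that this rule takes is not reported here. A comparison with calls made by the authors was also planned, but the table used here holds only FPKM values, so it was not applicable.

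Alternatives chosen before the data were examined were other pseudocounts (1 and 0.1), no filter or a mean of at least 5, quantile normalization, median centring, the replicate number as a block, leaving out each library, limma without the trend or with robust estimation, stricter thresholds, and the other list tests. Camera was not run with the variance alternatives. After seeing the data, 3 alternatives were added, which left out intron-nested genes, left out joined rows, or removed a trend on gene length and GC content together with the median. Length, GC content and intron position came from GENCODE 29 by gene symbol. That annotation is of another build than the authors', so no coordinates are given. Length and GC content were known for 8827 of the tested rows (91.1%).

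The fit was tested on simulated data made from the means and spreads of these 9694 genes. Genes were drawn independently of each other. Of them, 68 were changed by 0.5 log2, 66 by 1 and 66 by 2, in both directions. The fit called 14.7% of genes changed by 0.5 log2, 65.2% of those changed by 1 and 89.4% of those changed by 2. It called 9 unchanged genes (0.0948%). A shifted list of 40 genes was called, and 0 of 20 unchanged lists were. Independent draws cannot show how camera behaves for lists of correlated genes. Far fewer genes were changed than were called in the real data, so these rates may not carry over. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.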

Results

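Gene expression was measured by RNA sequencing in MIA PaCa-2 cells, an established pancreatic carcinoma line. The cells had the empty pCDH vector (n = 3) or overexpression of LINC00901 (n = 3). Total RNA was the starting material, and how the libraries were selected from it was not examined here. LINC00901 is a long noncoding RNA gene on chromosome 3. FPKM values summed to 87162, 87187 and 88738 in the vector libraries and to 128538, 128315 and 127768 in the overexpression libraries. The 10 highest rows took 5.16% ± 0.186 (SD, n = 3) of the vector sum and 7.79% ± 0.441 (SD, n = 3) of the overexpression sum. Rows above 0 numbered 12807, 12728 and 12733 in the vector libraries, against 13276, 13276 and 13428 in the overexpression libraries. The depth behind these values is unknown.

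The level of LINC00901 itself was not analysed here, since 0 rows name it, so the groups are as labelled and the overexpression was not checked. No member of the list of genes around LINC00901 was high enough to be tested. LSAMP, GAP43, IGSF11 and ZBTB20 had a row, and the highest value among them was 0.85 FPKM, for GAP43 in vector replicate 2.

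The comparison asked which genes differ between cells with LINC00901 overexpression and cells with the vector. Most tested members of the lists of immediate early, ribosomal protein, oxidative phosphorylation, hypoxia and glycolysis, and interferon-stimulated genes were higher in the overexpression libraries on the unscaled values. With the length and GC correction this no longer held for hypoxia and glycolysis (12 of 26 higher, 3 lower) and interferon-stimulated genes (11 of 25 higher, 0 lower). Both lists still passed camera upward with that correction (camera adjusted p = 0.00663 and 0.00525). Unscaled, the 5 lists passed camera at its preset correlation of 0.01. They did not pass with an estimated correlation (camera adjusted p = 0.149, 0.137, 0.178, 0.175 and 0.149), and hypoxia and glycolysis had 2 members lower. The estimate for interferon-stimulated genes was -0.0171, below the preset, so correlation between members does not account for the loss of that call. For the other lists, how far correlation accounts for the loss was not tested. FOS, a subunit of the AP-1 transcription factor, stood at 46.9 ± 0.772 FPKM (SD, n = 3) against 0.490 ± 0.111 in the vector libraries. SYTL2, a Rab27 effector in vesicle traffic, showed the largest fall by the rule for named genes, from 16.4 ± 1.16 to 1.58 ± 0.132 FPKM (SD, n = 3). In limma, 4773 of 9694 genes passed an adjusted p of 0.05, 3621 of them higher and 1152 lower in the overexpression libraries. The median gene was higher by 0.27 log2 (1.20-fold), and the log2 changes of genes below are relative to it. With each library centred on its median the split was 2331 higher and 1866 lower, with quantile normalization 1865 and 2024, and with the length and GC correction 1743 and 1736. Unscaled and median-centred values called 3483 genes in the same direction, 2331 higher and 1152 lower. Centring shifts all genes of a library alike, so this overlap is largely given in advance. With the length and GC correction as well, 2600 genes were called in the same direction, 1599 higher and 1001 lower. The groups did not overlap for 60.6% of tested genes, where chance gives 10%.

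MYC, the oncogenic transcription factor, and IGF2BP2, an RNA-binding protein that reads N6-methyladenosine, were both higher in the overexpression libraries. MYC stood at 15.9 ± 2.32 FPKM against 6.48 ± 0.560 (SD, n = 3), a relative log2 change of 0.96 (limma adjusted p = 0.000514). IGF2BP2 stood at 7.33 ± 0.437 against 2.30 ± 0.170 FPKM (SD, n = 3), a relative log2 change of 1.22 (limma adjusted p = 0.000168). The paralogue IGF2BP3 did not pass the test, with 12.5 ± 0.246 against 12.1 ± 2.79 FPKM (SD, n = 3) and a limma adjusted p of 0.778. Its difference was 0.06 log2 unscaled and -0.15 log2 after median centring, so the sign of the IGF2BP3 level depends on the scaling. Without vector replicate 1 it was -0.14 log2. IGF2BP1 lay below the filter, at 0.153 ± 0.0153 against 0.430 ± 0.0656 FPKM (SD, n = 3), and was not tested in the main fit. Its values were lower in every overexpression library (0.17, 0.15 and 0.14 FPKM) than in any vector library (0.42, 0.37 and 0.5).

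Immediate early genes, which cells switch on within minutes of a stimulus, formed the list with the largest median change. Of 20 tested members 18 were higher and 0 lower, and 18 passed adjusted over the list alone. After median centring 17 were higher, and with the length and GC correction 14 of 17. FOS rose by a relative log2 of 5.32. EGR1, a zinc finger transcription factor, rose by 3.79, from 2.57 ± 0.752 to 49.4 ± 1.38 FPKM (SD, n = 3), and JUNB, an AP-1 subunit, by 3.33, from 2.51 ± 0.674 to 35.4 ± 4.48. EGR3 was listed at 0 in each vector library and stood at 5.41, 4.32 and 4.54 FPKM in the overexpression libraries. The list passed camera (adjusted p = 8.57e-08), but not with an estimated correlation (adjusted p = 0.149).

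Other early-response genes were among the 12 largest rises. The nuclear receptor NR4A1 stood at 5.49 ± 1.23 against 0.177 ± 0.0651 FPKM, and the mRNA decay factor ZFP36 at 9.97 ± 1.79 against 0.847 ± 0.595 FPKM (SD, n = 3). PPP1R15A, which directs dephosphorylation of the initiation factor eIF2α, stood at 14.1 ± 2.40 against 1.36 ± 0.608 FPKM (SD, n = 3). The remaining rises were GLRX5, a mitochondrial glutaredoxin (relative log2 3.49), DNAJC8, a splicing-associated J-domain protein (3.03), RPL29, CREB3L3 and ARF6. RPL29, a ribosomal protein, varied widely among the overexpression libraries, at 61.25, 105.77 and 28.00 FPKM, against 4.98, 2.69 and 4.79. CREB3L3, a membrane-bound transcription factor, was listed at 0.80, 0.00 and 0.52 FPKM in the vector libraries and at 9.31, 12.97 and 10.29 in the others. The small GTPase ARF6 was listed at 0.00, 6.02 and 0.00 FPKM in the vector libraries and at 17.04, 14.10 and 23.82 in the overexpression libraries. Its unscaled log2 change was 3.97, and 3.35 without vector replicate 1 or 3 and 5.20 without vector replicate 2.

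**Figure D1:**
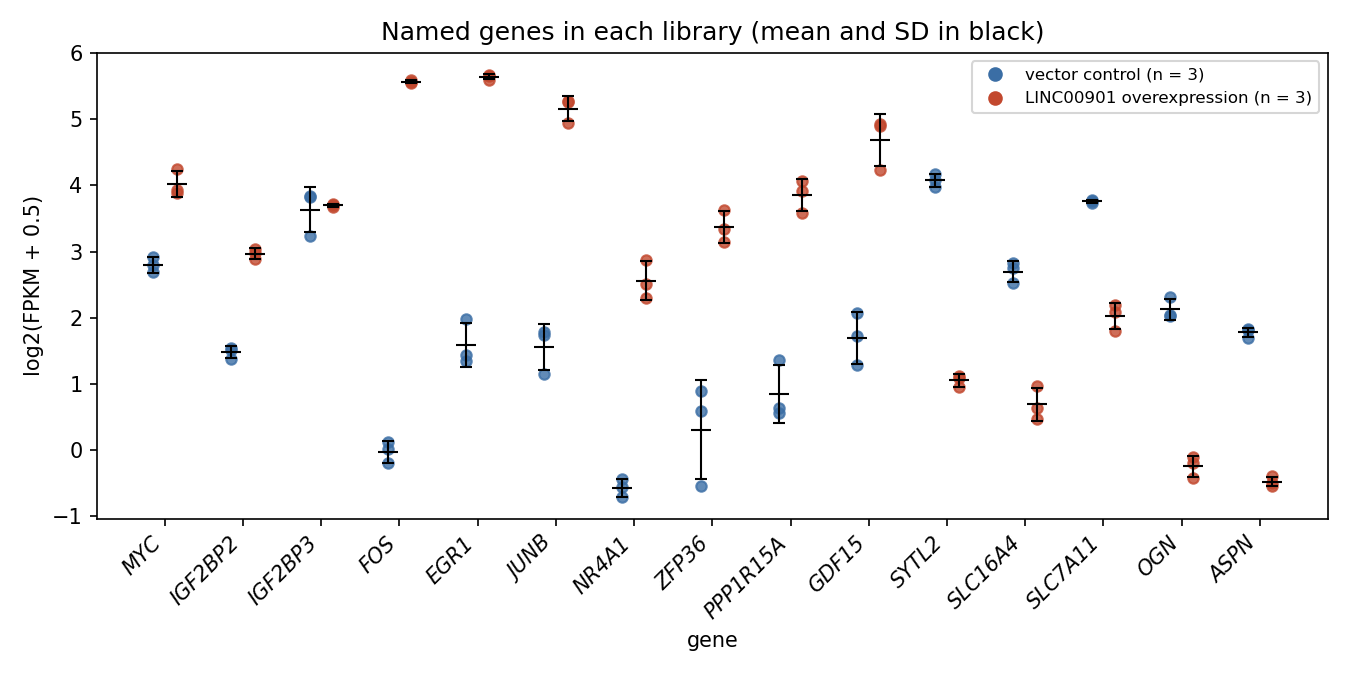
Values of 15 named genes in each library, as log2(FPKM + 0.5), for vector (blue, n = 3) and overexpression libraries (red, n = 3), with the mean and SD in black. FOS stands at 46.9 against 0.490 FPKM and SYTL2 at 1.58 against 16.4, while the IGF2BP3 groups overlap.

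Genes that fell included the monocarboxylate transporter SLC16A4, at 1.13 ± 0.294 against 6.02 ± 0.702 FPKM, and the histone gene HIST1H2BI, at 0.823 ± 0.673 against 5.93 ± 3.64 (SD, n = 3). The calcium-binding protein S100P was listed at 1.23, 0.00 and 0.47 FPKM, against 6.87, 3.30 and 2.15. OGN and ASPN, small leucine-rich proteoglycans of the matrix, fell to 0.350 ± 0.0917 and 0.220 ± 0.0361 FPKM from 3.88 ± 0.492 and 2.94 ± 0.165 (SD, n = 3). Both lie inside introns of CENPP, an expressed gene. ANGPTL1 (relative log2 -2.27) also lies inside an intron of an expressed gene, RALGPS2, and the taste receptor TAS2R30 (-2.28) inside a low or unlisted gene, PRH1. The syntaxin gene STX19 changed by a relative log2 of -2.35. The joined row of the alkaline phosphatases ALPI;ALPG was listed at 1.64, 0.00 and 0.00 FPKM against 3.64, 3.50 and 3.91, and its unscaled log2 change of -2.36 became -3.06 without overexpression replicate 1.

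For EIF2S3B and ABHD13, also among the 12 largest falls, the call depended on single libraries. EIF2S3B, a copy of an initiation factor gene whose reads could be shared with its paralogue, stood at 1.60, 0.20 and 2.22 FPKM against 12.71, 3.21 and 11.35. Its limma adjusted p of 0.0207 became 0.0636 without vector replicate 1 and 0.0637 without vector replicate 3, and its unscaled log2 change of -2.39 became -1.80 without overexpression replicate 2. ABHD13 was listed at 0.00, 0.00 and 2.76 FPKM against 3.24, 3.80 and 4.29. Its limma adjusted p of 0.0378 became 0.111 without overexpression replicate 1 or 2 and 0.0745, 0.0883 and 0.0923 without vector replicates 1, 2 and 3. Without overexpression replicate 3 its unscaled log2 change of -2.19 became -3.09. The ABHD13 level had an adjusted p of 0.0592 with the length and GC correction and 0.0570 with no filter.

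Ribosomal protein genes were higher almost throughout. Of 40 tested, 38 were higher and 0 lower (39 passed adjusted over the list alone), and 36 were higher after median centring. RPL35 rose from 48.3 ± 3.84 to 182 ± 12.8 FPKM (SD, n = 3) and RPL8 from 79.3 ± 2.23 to 277 ± 13.2. The camera adjusted p was 2.44e-13, and with an estimated correlation the adjusted p was 0.137. Short genes were shifted upward in general, with a median log2 change of 0.60 in the 1766 shortest genes against 0.05 in the 1766 longest. The list kept 32 of 39 members higher with the length and GC correction. Genes of high level were shifted upward too, with a median of 0.55 in the 1766 highest against 0.09 in the 1766 lowest. The correction has no term for level. Whether this list or others moved beyond genes of like level was not tested.

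Of 30 nuclear genes of oxidative phosphorylation, 26 were higher and 0 lower (27 adjusted over the list alone), with 21 and 0 after median centring and 15 and 0 of 23 with the length and GC correction. NDUFA1, a complex I subunit, rose from 30.5 ± 1.87 to 94.1 ± 6.93 FPKM (SD, n = 3), a relative log2 change of 1.34, and the cytochrome c oxidase subunit gene COX5B rose by 0.92. Of 31 hypoxia and glycolysis genes, 23 were higher and 2 lower (26 adjusted over the list alone). The counts were 19 and 3 after median centring, and 12 and 3 of 26 with the length and GC correction. ANKRD37, a hypoxia-induced gene, rose by a relative log2 of 1.94, and the aldolase gene ALDOC by 1.67. The members that fell were PFKFB3, which makes the activator of phosphofructokinase, and the neuronal enolase ENO2, named after their values were seen. The camera adjusted p was 3.75e-05 for oxidative phosphorylation and 0.00125 for hypoxia and glycolysis. With an estimated correlation the adjusted p was 0.178 and 0.175, respectively, and with quantile normalization that of hypoxia and glycolysis was 0.0805 (range over 16 alternatives 0.000303 to 0.0805).

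Of 21 cholesterol biosynthesis genes, 13 were higher and 0 lower (16 adjusted over the list alone), with 8 and 0 after median centring and 6 and 0 of 18 with the length and GC correction. The sterol reductase gene DHCR7 rose by a relative log2 of 0.96 and PMVK, a mevalonate pathway kinase gene, by 0.88. Of 13 fatty acid synthesis genes, 11 were higher and 0 lower (11 adjusted over the list alone), but 3 and 0 after median centring and 3 and 0 of 12 with the length and GC correction. SCD, the stearoyl-CoA desaturase gene, rose from 43.8 ± 1.67 to 97.2 ± 3.29 FPKM (SD, n = 3). The camera adjusted p was 0.0156 for cholesterol and 0.0442 for fatty acid synthesis, and with an estimated correlation the adjusted p was 0.406 and 0.240. The cholesterol call was lost with a mean of at least 5 (adjusted p = 0.197, range over 16 alternatives 0.00619 to 0.197). The fatty acid call was lost without vector replicate 1 (adjusted p = 0.0897), without vector replicate 2 (0.0627) and without overexpression replicate 3 (0.0689). It was also lost with median centring (0.0725), the replicate block (0.0564), quantile normalization (0.233) and a mean of at least 5 (0.124), over a range of 0.00479 to 0.233.

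Of 30 interferon-stimulated genes, 20 were higher and 0 lower (23 adjusted over the list alone). After median centring 17 were higher and 1 lower, and with the length and GC correction 11 and 0 of 25. IFI6, the member with the largest unscaled log2 change, was listed at 3.99, 1.78 and 0.00 FPKM in the vector libraries and at 7.34, 10.23 and 8.91 in the overexpression libraries. Its limma adjusted p of 0.0301 became 0.0551 without vector replicate 2 and 0.0644, 0.0825 and 0.0719 without overexpression replicates 1, 2 and 3. Its unscaled log2 change of 2.42 became 3.11 without vector replicate 1 and 1.53 without vector replicate 3. The IFI6 level had an adjusted p of 0.0993 with the length and GC correction and 0.0695 with a pseudocount of 0.1. OASL, an oligoadenylate synthetase-like gene, stood at 6.37 ± 0.586 against 0.943 ± 0.620 FPKM and the ubiquitin-like modifier gene ISG15 at 26.9 ± 0.513 against 6.14 ± 0.494 (SD, n = 3). With the length and GC correction the log2 change of OASL was 2.06 and that of IFI6 was 1.75. The camera adjusted p was 0.00127, and with an estimated correlation the adjusted p was 0.149.

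Stress-response genes moved in both directions. Of 28 integrated stress response and unfolded protein response genes, 19 were higher and 2 lower (22 adjusted over the list alone), with 14 and 2 after median centring and 10 and 3 of 27 with the length and GC correction. CEBPB rose from 1.70 ± 0.732 to 7.94 ± 1.58 FPKM (SD, n = 3), and the joined row DDIT3;AC022506, which holds the stress factor CHOP, rose by a relative log2 of 1.55. SLC7A11, the cystine transporter, fell from 13.0 ± 0.195 to 3.60 ± 0.545 FPKM (SD, n = 3), and PSPH, of serine synthesis and named after its values were seen, fell too. The camera adjusted p was 0.0156, and 0.227 was the adjusted p with an estimated correlation. Over 16 alternatives it ranged from 0.00274 to 0.210, and the call was lost with a mean of at least 5 (0.210), quantile normalization (0.20) and the length and GC correction (0.0893).

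Of 29 replication-dependent histone genes, 20 were higher and 1 lower (25 adjusted over the list alone), with 17 and 2 after median centring. HIST1H2AE stood at 58.0 ± 14.1 against 16.0 ± 3.64 FPKM and HIST1H4E at 82.2 ± 3.22 against 25.4 ± 1.36 (SD, n = 3), while HIST1H2AC, named after its values were seen, was lower. The camera adjusted p was 0.000795, and the adjusted p with an estimated correlation was 0.240. With quantile normalization it was 0.392 and with the length and GC correction 0.533, where 7 of 24 members were higher and 3 lower (range over 16 alternatives 1.18e-05 to 0.533). HIST1H2BI, among the 12 largest falls, is also a histone gene of this kind but was not a member of the list. Near-identical histone genes can share reads, so single members are uncertain.

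**Figure D2:**
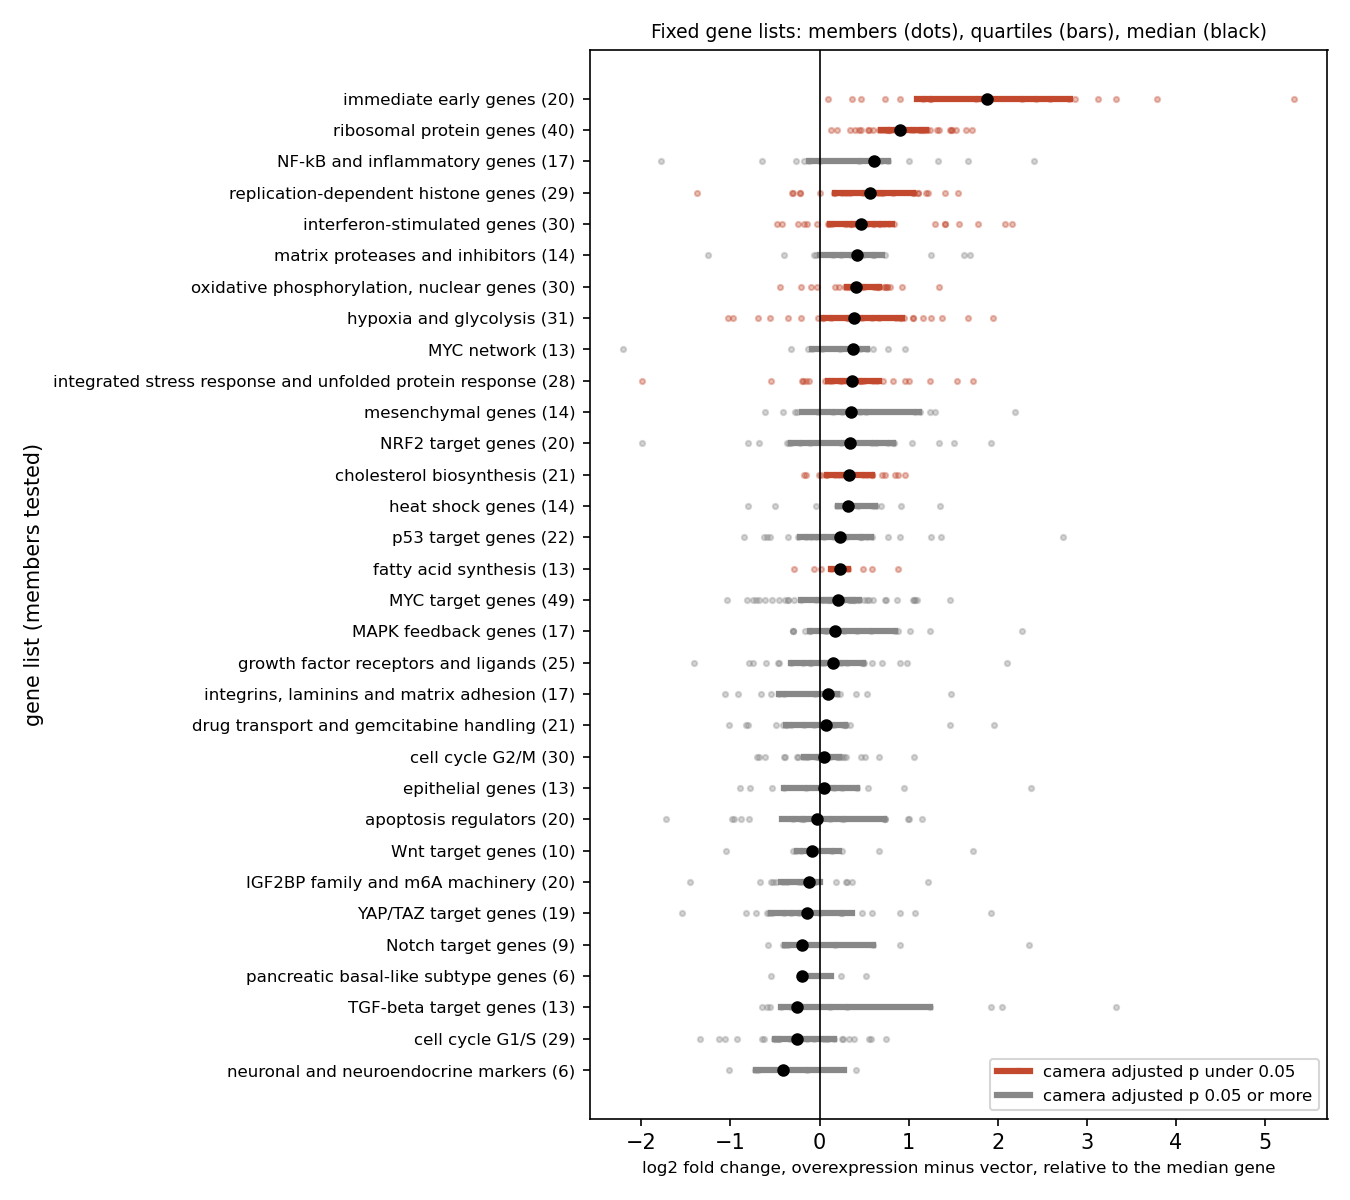
Relative log2 change (overexpression minus vector, minus the median gene) of the tested members of 32 fixed gene lists. Dots are genes, bars span the quartiles and black points are medians, and red marks the 9 lists past a camera adjusted p of 0.05, of which 0 pass with an estimated correlation.

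MYC target genes did not pass camera as a list (adjusted p = 0.132). Of 49, 27 were higher and 5 lower (35 adjusted over the list alone), and after median centring 18 were higher and 8 lower. With the length and GC correction 12 of 40 were higher and 8 lower. The joined row NME1-NME2;NME1;NME2, of nucleoside diphosphate kinases, rose by a relative log2 of 1.47. In the MYC network, 8 of 13 genes were higher and 1 lower (camera adjusted p = 0.401). The counts were 4 and 1 after median centring, and 1 and 1 of 11 with the length and GC correction. The lower gene was MYCN, at 1.29 ± 1.46 against 5.45 ± 2.68 FPKM (SD, n = 3). Its limma adjusted p of 0.0258 became 0.0754 without vector replicate 3 and 0.0803 and 0.0756 without overexpression replicates 2 and 3. Without overexpression replicate 1 its unscaled log2 change of -1.94 became -2.56. Among IGF2BP family and N6-methyladenosine genes, 4 of 20 were higher and 2 lower, but 2 and 4 after median centring, so the direction depends on the scaling (camera adjusted p = 0.734). RBM15, a subunit of the methyltransferase complex, fell from 8.72 ± 2.07 to 3.49 ± 0.505 FPKM (SD, n = 3).

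Cell cycle lists did not pass camera. In G1/S, 10 of 29 were higher and 6 lower unscaled, and 6 and 10 after median centring, so the direction of this list depends on the scaling (camera adjusted p = 0.228). The cyclin gene CCNE2 changed by a relative log2 of -1.35 and the kinase gene CDK4 rose by 0.75. In G2/M, 15 of 30 were higher and 0 lower, and 9 and 2 after median centring (camera adjusted p = 0.211). The phosphatase gene CDC25B rose by 1.06 (limma adjusted p = 0.00716), and the CDC25B level had an adjusted p of 0.0708 with quantile normalization (range over the alternatives 0.000742 to 0.0708). Among p53 targets 11 of 22 were higher and 1 lower, and 6 and 4 after median centring (camera adjusted p = 0.568), with the cytokine gene GDF15 at 25.9 ± 6.49 against 2.82 ± 0.875 FPKM (SD, n = 3). Among apoptosis regulators 8 of 20 were higher and 2 lower, and 4 and 3 after median centring (camera adjusted p = 0.883). XIAP, a caspase inhibitor, fell from 9.62 ± 0.406 to 3.41 ± 1.68 FPKM (SD, n = 3), and the death ligand gene TNFSF10 rose from 2.11 ± 0.599 to 5.67 ± 0.340.

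In signalling lists, 10 of 17 NF-kB and inflammatory genes were higher and 1 lower, and 8 and 1 after median centring (camera adjusted p = 0.132). The chemokine gene CXCL2 stood at 10.6 ± 0.281 against 1.24 ± 0.121 FPKM (SD, n = 3). Of 17 MAPK feedback genes 9 were higher and 0 lower, and 5 and 1 after median centring (0.228 by camera, adjusted), and IER3 rose by a relative log2 of 2.27. Of 19 YAP/TAZ targets 6 were higher and 2 lower, but 5 and 5 after median centring and 3 and 5 with the length and GC correction (camera adjusted p = 0.838). Their member CCN2 was listed at 0.00, 0.34 and 0.15 FPKM in the vector libraries and at 3.32, 1.80 and 2.43 in the others. Of 13 TGF-beta targets 5 were higher and 1 lower, and 5 and 3 after median centring (camera adjusted p = 0.868). Of 10 Wnt targets 2 were higher and 1 lower, and 2 and 2 after median centring (camera adjusted p = 0.931). Of 9 Notch targets 2 were higher and 0 lower, but 2 and 3 after median centring (camera adjusted p = 0.868). Of 20 NRF2 targets 11 were higher and 2 lower, and 11 and 3 after median centring (camera adjusted p = 0.196). They include FTL, the ferritin light chain gene, at 1430 ± 182 against 313 ± 22.9 FPKM (SD, n = 3). Of 14 heat shock genes 7 were higher and 0 lower, and 6 and 1 after median centring, and HSPB1 rose by 1.35. The camera adjusted p of the heat shock list was 0.0901, and with an estimated correlation the adjusted p was 0.477. With the length and GC correction 6 of 12 were higher and 0 lower (camera adjusted p = 0.0375).

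Of 14 mesenchymal genes 9 were higher and 1 lower, and 7 and 2 after median centring (camera adjusted p = 0.121). SNAI2, a repressor of epithelial genes, stood at 6.34 ± 0.626 against 0.757 ± 0.207 FPKM (SD, n = 3). Of 13 epithelial genes 6 were higher and 2 lower, but 3 and 3 after median centring (camera adjusted p = 0.868), with KRT19 at 24.0 ± 1.06 against 3.71 ± 1.95 FPKM (SD, n = 3). Of 14 matrix proteases and inhibitors 9 were higher and 1 lower, and 6 and 2 after median centring (camera adjusted p = 0.0716). In that list the joined stromelysin row MMP3;MMP10 rose by a relative log2 of 1.69 and PLAU, the urokinase gene, by 1.62. Of 17 integrin, laminin and adhesion genes 8 were higher and 3 lower, but 3 and 5 both after median centring and with the length and GC correction (camera adjusted p = 0.987), and SDC1 rose by 1.48. Of 25 growth factor receptors and ligands 12 were higher and 4 lower, 9 and 5 after median centring and 4 and 5 with the length and GC correction (0.868 by camera, adjusted), and the joined row IGF2;INS;INS-IGF2 rose by 2.11. Of 21 drug transport and gemcitabine genes 8 were higher and 3 lower, and 5 and 4 after median centring (camera adjusted p = 0.937), with the cytidine deaminase gene CDA at 10.6 ± 1.31 against 2.10 ± 1.52 FPKM (SD, n = 3).

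Subtype and other-lineage markers were few. Of 6 basal-like subtype genes 2 were higher and 1 lower, and 1 and 1 after median centring (camera adjusted p = 0.868), and CTSV rose by a relative log2 of 0.52. Of 3 tested classical subtype genes 1 was higher and 0 lower. Of 6 neuronal and neuroendocrine markers 2 were higher and 3 lower (camera adjusted p = 0.711), with the secretogranin gene SCG2 at 11.2 ± 1.16 against 1.58 ± 0.339 FPKM (SD, n = 3). Of 4 markers of fibroblasts, endothelium and blood 2 were higher and 1 lower, and 2 and 2 after median centring. COL1A1 rose by 0.76, and the other higher marker was the joined row EIF4A1;CD68;SENP3. COL1A2, at a higher level, stood at 13.1 ± 2.69 against 18.1 ± 0.465 FPKM (SD, n = 3), a relative log2 change of -0.74. Its limma adjusted p of 0.0339 became 0.0784, 0.0674 and 0.0795 without vector replicates 1, 2 and 3, and 0.0605 and 0.0792 without overexpression replicates 1 and 3. The lists of mitochondrially encoded genes, small nuclear and nucleolar RNAs and long noncoding RNAs had 0 tested members.

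**Figure D3:**
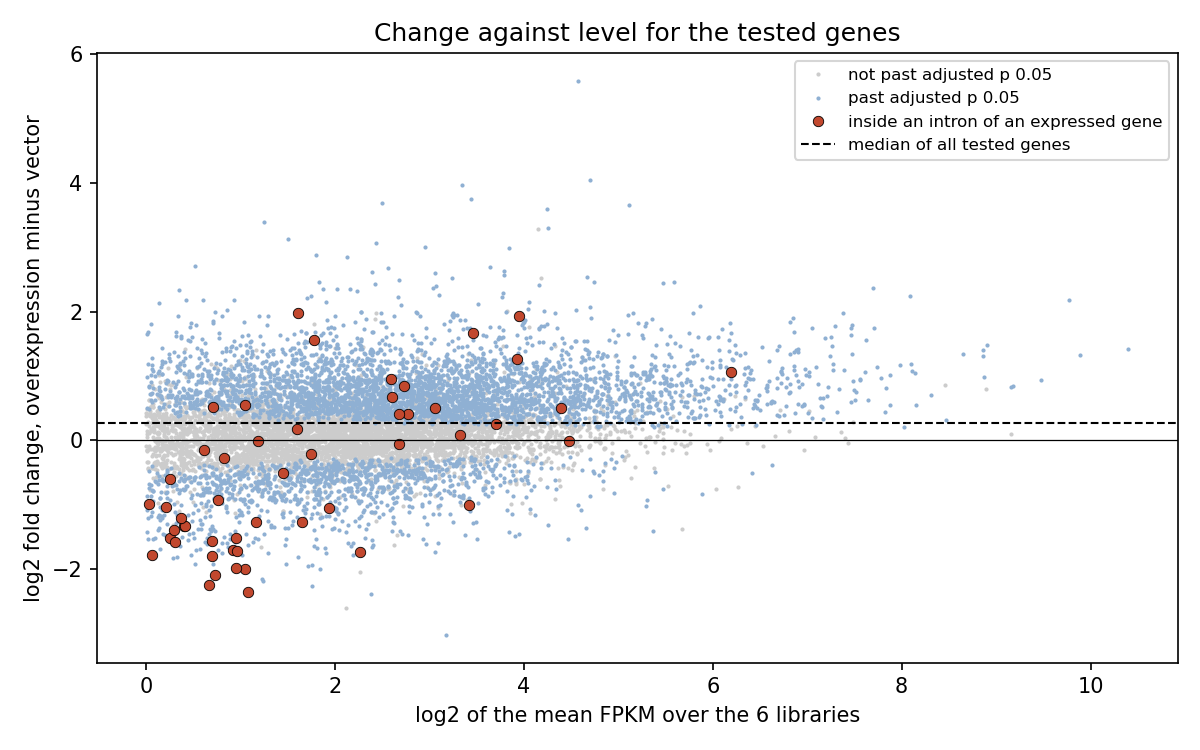
Log2 fold change (overexpression minus vector, unscaled) against log2 of the mean FPKM over 6 libraries for the 9694 tested genes, with genes past an adjusted p of 0.05 in blue and genes inside introns of expressed genes in red. The dashed line marks the median of 0.27, and the red points lie lower at low levels.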

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

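The alternatives with the length and GC correction, without intron-nested genes and without joined rows were chosen after seeing the data. With a mean of at least 5, 2818 genes passed (2396 higher, 422 lower, of 4830 tested). An absolute log2 change of at least 1 left 1223 (963 higher, 260 lower), and an adjusted p under 0.01 left 2881 (2287 genes higher in overexpression, 594 genes lower in overexpression). Fewer genes pass these by construction. Quantile normalization gave 1865 higher and 2024 lower, median centring 2331 and 1866, and the length and GC correction 1743 and 1736. These methods remove all or most of the shift of the median gene, which was 0.27 log2 unscaled and 0.06 after median centring. The split of calls is therefore not a property of the cells that these values can fix. Leaving out each library gave 3580 to 4358 genes (2768 to 3371 higher, 812 to 1004 lower). MYC kept its direction and its call under 18 alternatives (log2 0.83 to 1.29) and IGF2BP2 under 17 (1.24 to 1.63). The IGF2BP3 level turned to -0.31 with quantile normalization, -0.15 with median centring, -0.0747 with the length and GC correction and, over left-out libraries, lay between -0.14 (without vector replicate 1) and 0.17, and the EIF4A1;CD68;SENP3 level to -0.0266 with quantile normalization. The cause was not tested. Among the other values of single named genes, 2329 kept their direction and their side of the threshold and 111 kept only their direction. Of the 9 lists past camera, 0 passed with an estimated correlation, where the adjusted p starts at 0.137. Fry, which compares with no other genes, passed 29 lists. It was run on the unscaled values, so the shift of the median gene adds to its count. The IGF2BP family and N6-methyladenosine list passed fry upward (fry adjusted p = 0.00609), although its median lay 0.12 log2 below the median gene. The estimated correlation lay below the preset 0.01 for interferon-stimulated (-0.0171), fatty acid synthesis (-0.0263) and integrated stress response genes (0.00897). Correlation between members therefore does not account for the loss of those calls. Among the other lists it lay between 0.0120 (hypoxia and glycolysis) and 0.0888 (cholesterol biosynthesis). How far correlation accounts for the loss of their calls was not tested. The replicate block gave 4227 genes (3262 higher, 965 lower). The deviations of same-numbered libraries correlated at -0.0370, -0.00574 and -0.00503, and those of other pairs at -0.0149 to 0.0206. No shared effect of the replicate number was visible. Whether same-numbered libraries were handled together stays open. Camera has no values for limma without the trend or with robust estimation, and LINC00901 has no value under any setting. The unknown depth leaves counting error in low genes unmeasured.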

Other observations

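The zinc finger, translation, proteasome, splicing, circadian, kinesin and intron-nested groups were chosen after the values were seen, as were the tests of length and GC content, unspliced RNA, genomic DNA and handling and the bounds set for median centring, the splits and the batch, while median centring itself, the immediate early list and the test against host level were fixed before their results were seen. Genes with ZNF names, mostly zinc finger transcription factors, were lower as a group. Of 250 tested, 68 were lower and 39 higher (camera adjusted p = 4.74e-09, and adjusted p = 0.0437 with an estimated correlation). After median centring 92 were lower and 17 higher, and with the length and GC correction 85 and 16 (camera adjusted p = 4.97e-06). ZNF678 stood at 0.263 ± 0.123 against 1.94 ± 0.0981 FPKM (SD, n = 3) and ZNF254 at 2.01 ± 0.283 against 7.13 ± 1.40. Mitochondrial ribosomal protein genes were higher, with 40 of 61 higher and 0 lower, and 28 and 0 after median centring (camera adjusted p = 4.91e-05, and adjusted p = 0.0419 with an estimated correlation). Of 33 proteasome genes 23 were higher and 1 lower, and 16 and 2 after median centring (camera adjusted p = 0.000668, and adjusted p = 0.142 with an estimated correlation). Of 57 translation initiation and elongation factor genes 32 were higher and 2 lower, and 25 and 5 after median centring (0.000943 by camera, and adjusted p = 0.0679 with an estimated correlation).

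Splicing factor genes moved apart. SRSF1 stood at 11.3 ± 3.08 against 33.0 ± 5.34 FPKM, SRSF3 at 22.3 ± 1.80 against 60.2 ± 5.40 and SRSF10 at 3.09 ± 0.778 against 9.10 ± 2.20, all lower with overexpression, while SRSF2 stood at 24.97 ± 2.68 against 6.76 ± 1.44 (SD, n = 3). Of 34 SR and hnRNP genes 12 were higher and 8 lower (camera adjusted p = 0.493), a balance that turns to 8 and 10 after median centring and to 5 and 10 of 30 with the length and GC correction. Of 24 CDC-like kinase and other splicing regulator genes 3 were higher and 8 lower, with 0 and 12 after median centring and 0 and 7 of 20 with the length and GC correction (camera adjusted p = 0.00212, and adjusted p = 0.0851 with an estimated correlation). Of 12 circadian genes 7 were higher and 0 lower, and 6 and 2 after median centring (camera adjusted p = 0.125, and adjusted p = 0.203 with an estimated correlation). With the length and GC correction 6 were higher and 1 lower (camera adjusted p = 0.0352). Among them NR1D1 stood at 14.6 ± 3.43 against 1.96 ± 0.193 FPKM and TEF at 8.04 ± 0.590 against 1.65 ± 0.305 (SD, n = 3). Of 29 kinesin genes 8 were higher and 4 lower (camera adjusted p = 0.293), a balance that turns to 5 and 7 after median centring and to 1 and 6 with the length and GC correction.

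Nearly 1 in 2 tested genes (49.2%) differed between the groups. A single scale factor per library does not account for this, since 43.3% of genes still passed after median centring. Trends on gene length and GC content do not account for it as a whole either, since 39.4% of 8827 genes passed after these were removed. The 10 splits of the libraries are too few for a share under 0.05, and the real split gave 4773 genes against at most 1 in any other. The labels give 0 batches that hold both groups, so a culture or library batch and LINC00901 cannot be told apart, and the effect of LINC00901 stays open as well.

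Genes inside introns of expressed genes were lower in the overexpression libraries when their level was low, while above 3 FPKM 23 nested genes had a median of 0.41 against 0.33 for others. Among genes with a mean of 0.3 to 3 FPKM, a window chosen after seeing the data, 63 nested genes had a median log2 change 1.07 below that of 3877 other genes (difference -1.07, permutation p = 1e-05, the smallest 100000 permutations can give), and 59 of 63 were lower. Olfactory receptor genes gained 0.0129 FPKM on average in the vector libraries, 1.36% of the median gain of nested genes (0.95 FPKM). This argues against genomic DNA that adds alike to all genes as the main source of the gain. The 334 receptor genes had no level filter, however, while the nested genes did. The receptor sum was also higher in the vector libraries (6.84, 4.38 and 7.31 FPKM against 2.19, 1.78 and 1.62). Some genomic DNA is therefore not excluded. More unspliced host RNA in the vector libraries may account for the pattern. The difference of 0.65 from 65 genes in low or unlisted hosts (-0.65, permutation p = 2e-05) goes with that explanation. Those 65 genes, however, also lay below non-nested genes, with a median of -0.36 against 0.07. Of the 63 nested genes 56 lie on the strand opposite their host, and 53 of these were lower. Host RNA could add to them only if strand was ignored in counting, which was not examined here. The gain did not follow the host's level across genes (Spearman rho = -0.0816, Pearson r = -0.0986, permutation p = 0.5, 63 genes that are not independent replicates). That rho is what lower expression of the nested genes themselves, unrelated to the host, was said in advance to give. This explanation and that of unspliced host RNA both stay open.

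Immediate early genes rose with overexpression, 18 of 20 members. Length and GC trends do not account for this, since the median log2 change of the 15 called members with a known length was 1.95 after the correction (2.53 before) and 14 still passed. A medium change or other handling difference before harvest may raise these genes too. All 18 called members moved as either explanation predicts, and no value here separates handling from the overexpression itself, so the 2 cannot be told apart.

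Some rows had 1 library far from 2 that agreed (over 2 log2 from libraries within 0.5 log2 of each other), 59 in the vector and 30 in the overexpression libraries. TGOLN2 was listed at 35.64, 39.15 and 3.82 FPKM in the vector libraries and at 3.49, 6.73 and 31.81 in the overexpression libraries, and was chosen after its values were seen.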
